A study of Mus musculus with 48 samples.

How the data were processed

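RNA was measured in airspace macrophages recovered by bronchoalveolar lavage from 24 male mice (how these cells were separated from other lavage cells is not given in the sources used here, so values may include RNA of other cells), 12 wild type (WT) and 12 lacking Siglec-F (knockout, KO), a sialic acid-binding receptor of alveolar macrophages encoded by Siglecf. Per the labels, mice were naive, given saline and marked day 0, or were given bleomycin into the trachea at 2.5 units/kg and sampled 7, 14 or 21 days later, with 3 mice in each of the 8 groups. RNA was purified with RNeasy Micro Plus columns, 200 ng went into Universal Plus mRNA-Seq libraries with NuQuant, and libraries were sequenced as 150 bp paired ends.

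The deposited table holds expected counts from the authors, as estimated read counts per gene with fractions, for 24411 genes, with 1 column per mouse. Each mouse is listed with 2 sequencing runs, and the labels do not say whether a column sums both. The authors' notes name the mm10 build, bcl2fastq, DESeq2 and limma. The aligner and the counting tool are not given in the sources used here, nor is whether reads were assigned by strand, so values of overlapping or antisense genes are uncertain. The same holds for near-identical genes, such as the kallikreins, hemoglobins, Hspa1a and Hspa1b, Ear1 and Ear2, Ly6c2, Trim30b, Erdr1 and Tmem254b. Values were not whole numbers in 3.11 to 3.85% of entries, and no mitochondrial genes are in the table. A further 24 columns that belong to other samples were not used here.

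Expected counts were rounded to whole numbers. Totals ran from 24877049 to 47457085 counts per mouse. Genes were kept with edgeR 4.0.16 filterByExpr on the 8 groups, with a minimum count of 10 and a minimum total of 15, which left 12634 genes. Libraries were scaled with TMM factors, and 1 edgeR quasi-likelihood model with a mean for each of the 8 groups was fitted in R 4.3.3, with 16 residual degrees of freedom, a prior of 4.4 degrees of freedom and a common biological coefficient of variation of 0.21. The comparisons were KO against WT at each of the 4 times and averaged over them, bleomycin against naive at each day within each genotype, and the difference between the genotypes in that response at each day. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Levels are in CPM, edgeR's counts scaled to equal TMM-adjusted library totals, as mean ± SD over 3 mice, and log2 fold changes carry the model's SE. Where a group held 0 counts of a gene in its 3 libraries, the fold is a lower bound against 3 counts over the group. Such floors cover counting error only, and the reads carry no molecular identifiers, so they are not independent molecules.

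The comparisons, the gene lists, the rule for naming genes and all alternatives but those based on Rn45s were fixed before the data were examined. Gene groups were tested with 42 lists, of which 39 had at least 5 tested genes. The competitive test was camera from limma 3.58.1 with its preset correlation of 0.01, adjusted over the lists of a comparison. It was repeated with a correlation estimated from the data, and fry was run as a test of direction within a list. Members were also counted with p-values adjusted over the list alone. A list's level in a mouse is the mean of log2(CPM + 1) over its tested genes, compared by exact two-sided permutation tests, for which 3 mice against 3 cannot go below p = 0.1. The rule for naming genes takes, per comparison, the 6 highest and 6 lowest fold changes among called genes with a standard symbol. Such genes need a mean of at least 5 CPM in the highest of the groups compared, and no overlap of the mice. The overlap condition is dropped for averages and response differences. The rule adds up to 4 members with the smallest p of each described list and a fixed panel of 30 genes. Genes named outside it are said to be chosen after their values were seen. Gene positions came from GENCODE M21 for 23334 genes.

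The pipeline was tested on simulated counts made for KO against WT at day 14, with 200 of 12398 genes changed. It recovered 34.3% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 98.5% of those changed 4-fold. Of 142 calls 3 were false, a planted list was called, and 0 of 40 random lists were. Simulated genes varied independently of each other, unlike genes of the real mice. The list result therefore does not show how often lists of correlated genes are called by chance. Counting error was far below the spread between mice: chi-square per degree of freedom between mice of a group ran from 13.4 to 226.5.

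The alternatives tried were DESeq2 1.42.0, limma-voom, median-ratio scaling (RLE), no expression filter, a model of the compared groups alone, the mouse number as a block, counts thinned to equal totals, an estimated correlation and fry for the lists, and leaving out each library in turn. Alternatives added afterwards were a covariate for the share of Rn45s, a ribosomal RNA gene, and leaving out both libraries with the highest such share. Library numbers 1 to 12 are WT and 13 to 24 KO, so any effect of processing order is confounded with genotype. Within each genotype the numbers run through day 7, day 14, day 21 and naive in the same order. Such an effect is therefore confounded with bleomycin and time as well, alike in both genotypes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.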

Results

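Messenger RNA was profiled in airspace macrophages of WT and KO mice in the naive state and 7, 14 and 21 days after bleomycin, a drug that injures the lung and leads to fibrosis. There were 3 mice in each of 8 groups, and library totals ran from 24877049 to 47457085 counts. The comparisons ask how airspace macrophages change after lung injury, and whether loss of Siglec-F alters them at rest or during the injury and repair phases. Bleomycin accounted for most of the variation. The first principal component held 51.5% of the variance and placed the 6 naive mice between -98 and -89 and the 9 WT mice after bleomycin between 24.2 and 54.5. The 9 KO mice after bleomycin ranged from -23.8 to 58.9, because 2 mice of day 14 (3.5 and -19) and 1 of day 21 (-23.8) lay nearer the naive mice.

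**Figure D1:**
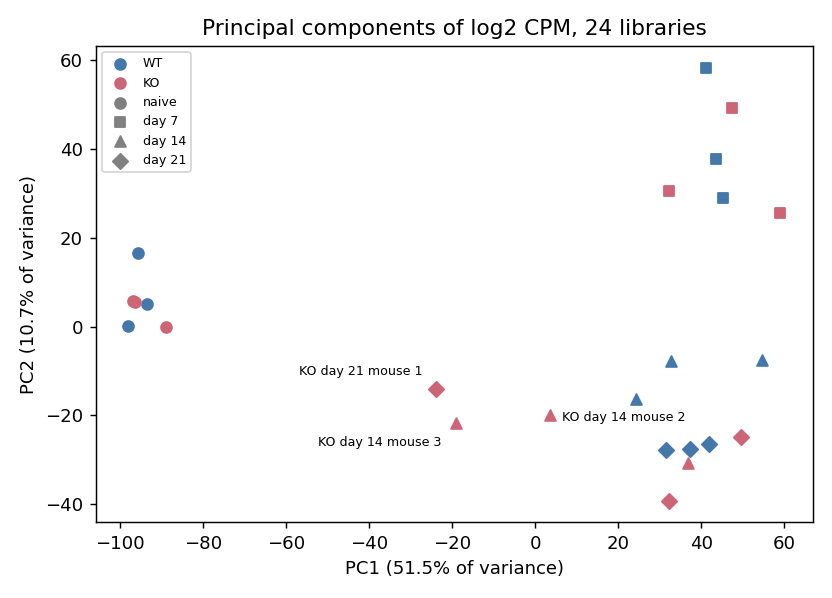
Principal components 1 (51.5% of the variance) and 2 (10.7%) of log2 CPM in the 24 libraries, 1 point per mouse, by genotype and time. The 6 naive mice sit apart on component 1, and KO mice at days 14 and 21 are spread more widely on it than WT mice.

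Siglecf (ENSMUSG00000039013.16; mm10 chromosome 7, 43351341 to 43359531) was almost absent from every KO library. KO libraries held 0 to 25 counts each, and KO naive mice averaged 0.341 ± 0.21 CPM (SD, n = 3) where the 3 WT naive mice had 403 to 481. The log2 fold change of KO against WT was -10.29 (SE 0.41) in naive mice (-10.9 without KO naive mouse 3), -9.18 (SE 0.43) at day 7, -10.12 (SE 0.47) at day 14 and -9.24 (SE 0.43) at day 21. In WT mice Siglecf itself fell after bleomycin, to 89.4 ± 21 CPM at day 7, 106 ± 43 at day 14 and 102 ± 17 at day 21. The falls were 4.86-fold, 4.1-fold and 4.25-fold, with an edgeR adjusted p of 1.8e-06 at day 7.

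In WT mice bleomycin raised genes of monocyte-derived and fibrosis-associated macrophages and lowered genes of resident alveolar macrophages. Spp1, which encodes the secreted matrix protein osteopontin, rose from 383 ± 55.3 CPM in naive mice to 3430 ± 502 at day 7, 13100 ± 1030 at day 14 and 16400 ± 1300 at day 21 (n = 3). Gpnmb, a membrane glycoprotein of lipid-handling macrophages, rose 2.02-fold, 2.98-fold and 2.44-fold on the same days. Arg1, which encodes the arginine-consuming enzyme arginase 1, rose from 0.321 ± 0.206 CPM to 238 ± 106, 150 ± 25.9 and 255 ± 55.3. The macrophage elastase gene Mmp12 rose with log2 fold changes of 3.98, 4.96 and 4.66, which were 4.86, 5.84 and 5.54 without WT naive mouse 3. The lipid receptor gene Trem2 rose 5.26-fold, 7.67-fold and 6.56-fold, and the fibronectin gene Fn1 rose 5.76-fold, 8.46-fold and 6.75-fold. The edgeR model called 4481 genes at day 7 (2552 higher, 1929 lower), 4059 at day 14 (2360 higher, 1699 lower) and 4102 at day 21 (2375 higher, 1727 lower), of 12634 tested. The 3 comparisons share the WT naive mice, so their overlap is not counted.

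Monocyte and interstitial macrophage genes appeared from near absence in WT airspaces. C1qa, a complement component of interstitial macrophages, went from 2.36 CPM in naive mice to 946 at day 7, 988 at day 14 and 663 at day 21. Ccr2, the receptor that brings monocytes out of bone marrow, rose from 4.61 CPM to 311, 112 and 64.9. Ly6c2, a marker of classical monocytes, had 0 counts in naive WT mice and reached 78.1 ± 12.7 CPM at day 7, at least 2750-fold higher. The lipid carrier gene Apoe rose 71.8-fold at day 14 and 47.1-fold at day 21. Of 18 recruited macrophage genes, 15, 16 and 16 rose on the 3 days, and of 13 interstitial macrophage genes 11 rose on each day. With an estimated correlation the camera adjusted p of the recruited list was 0.072 at day 7, 0.041 at day 14 and 0.045 at day 21, and that of the interstitial list 0.072, 0.023 and 0.028.

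Resident alveolar macrophage genes moved the other way in WT mice. Of 29 resident genes 23 fell at day 7, 17 at day 14 and 16 at day 21, while 3, 3 and 4 rose. The camera adjusted p of this list was 6.8e-09, 5.6e-05 and 0.00069, and 0.098, 0.14 and 0.25 with an estimated correlation, where it was not called. Pparg, the nuclear receptor that maintains these cells, fell 2.13-fold, 1.82-fold and 1.55-fold. Fabp1, a fatty acid-binding protein gene, went from 211 ± 59.1 to 9.27 ± 1.21 CPM at day 7. Krt79 went from 492 ± 79.4 to 31.1 ± 6.1 CPM at day 7, and Chil3, a chitinase-like lectin gene, was 3.2-fold lower. Of 24 fatty acid oxidation genes 17, 14 and 11 fell, among them Hadhb, which was 1.84-fold, 1.59-fold and 1.52-fold lower.

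Fibrosis, sterol, interferon and lysosome genes rose alongside. Of 21 fibrosis-associated macrophage genes 15, 15 and 16 rose on days 7, 14 and 21, with a camera adjusted p under an estimated correlation of 0.098, 0.023 and 0.028. Of 19 growth factor and TGF-beta family genes 11, 12 and 13 rose, including Pdgfb, a mitogen for fibroblasts, at 11.4-fold, 17.6-fold and 16-fold. All 24 tested cholesterol synthesis genes rose on each of the 3 days, with median log2 fold changes of 0.89, 1.12 and 1.4. With an estimated correlation the camera adjusted p of the sterol list was 0.2 and 0.085 at days 7 and 14, where it was not called, and 0.044 at day 21. Of 33 interferon-response genes 31, 30 and 24 rose, with the antiviral gene Oasl2 at 27.2-fold, 16-fold and 9.51-fold; with an estimated correlation the adjusted p was 0.098, 0.11 and 0.25. Of 29 lysosome genes 16, 20 and 19 rose.

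KO mice showed the same broad response to bleomycin. Spp1 went from 342 CPM in naive KO mice to 4800 at day 7, 10800 at day 14 and 11500 at day 21, which is 14-fold, 31.5-fold and 33.7-fold. Fn1 rose 11-fold, 14.7-fold and 16.3-fold and Mmp12 17.4-fold, 18-fold and 17-fold on the 3 days. Arg1 rose 464-fold at day 14, and C1qa 460-fold and 155-fold at days 7 and 14. Ccr2 rose 45.6-fold at day 7, 7.06-fold at day 14 and 8.79-fold at day 21. Gpnmb rose 1.62-fold at day 7 (edgeR adjusted p = 0.0062) and missed the threshold at day 14 (adjusted p = 0.088) and day 21 (adjusted p = 0.06). Resident genes fell in 23 of 29 at day 7, 7 at day 14 and 3 at day 21, and Fabp1 was 19.3-fold lower at day 7. Of 24 sterol genes 13, 24 and 19 rose. The edgeR model called 4308 genes at day 7 (2485 higher, 1823 lower), 2132 at day 14 (1521 higher, 611 lower) and 2765 at day 21 (1895 higher, 870 lower). The day 14 count was 1276 without KO day 14 mouse 1 and 1386 without KO naive mouse 2. The day 21 count was 1735 without KO day 21 mouse 2, 1779 without KO day 21 mouse 3 and 1391 in a model of the compared groups alone.

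Across genes, the WT and KO responses had Pearson's r of 0.88 at day 7, 0.82 at day 14 and 0.85 at day 21 and Spearman's rho of 0.81, 0.67 and 0.69. The pairs share no libraries, and genes are not independent replicates. Genes called in both genotypes with 1 sign numbered 3240, 1693 and 2070, against 8, 23 and 16 with opposite signs. Chance would give 502, 284 and 356 shared rises, where 1952, 1287 and 1517 were seen, and 278, 82 and 119 shared falls, where 1288, 406 and 553 were seen. Over genes called in WT with a WT log2 fold change of at least 1 in size, the median ratio of the KO to the WT log2 fold change was 0.95, 0.72 and 0.81. Choosing genes by their WT change lowers this ratio even where genotypes do not differ, so it does not measure a weaker KO response.

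**Figure D2:**
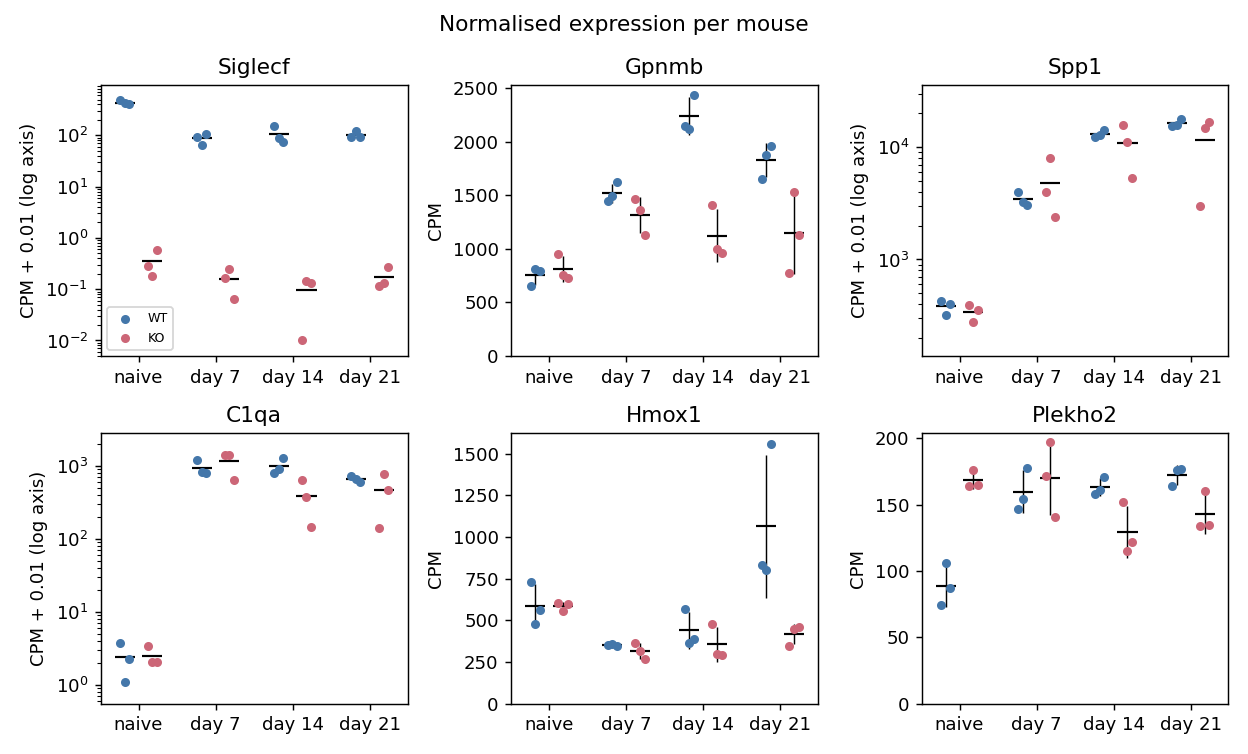
Level in CPM of Siglecf, Gpnmb, Spp1, C1qa, Hmox1 and Plekho2 in each of the 24 mice by genotype and time. Points are mice, horizontal bars group means and vertical bars SD; Siglecf, Spp1 and C1qa are on a log axis of CPM + 0.01 without an SD bar. Siglecf is near 0 in all KO mice, and mean Gpnmb at day 14 is 1120 CPM in KO and 2240 in WT mice.

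In naive mice, Rsrp1, Luc7l and Tsc22d3 were lower and Plekho2 was higher in KO than in WT samples. Rsrp1, an arginine- and serine-rich protein gene, was at 34.8 ± 16.7 CPM in KO and 208 ± 34 in WT mice (5.97-fold lower, n = 3, edgeR adjusted p = 0.011). Luc7l, a U1 splicing factor gene, was 2.82-fold lower, at 11.3 ± 1.41 against 32 ± 5.66 CPM (adjusted p = 0.00025). Tsc22d3, a leucine zipper protein gene, was 3.49-fold lower, and the heparan sulfate sulfotransferase gene Hs3st3b1 was 4.07-fold lower. Crem, a cAMP-response gene, had a log2 fold change of -1.92, and of -1.13 without WT naive mouse 1, where it was not called (edgeR adjusted p = 0.14), nor was it without KO mouse 1, 2 or 3 (0.14, 0.11 and 0.075). Plaur, the urokinase receptor gene, was at 204 ± 15.7 against 350 ± 36.3 CPM, and the heat shock gene Dnajb1 and the immediate-early gene Jun were 2.2-fold and 1.91-fold lower. Among genes higher in KO mice, Plekho2 was at 169 ± 6.73 against 88.9 ± 15.9 CPM (1.9-fold, adjusted p = 0.0021). The aspartic protease gene Napsa was 1.94-fold higher, the transcriptional repressor gene Bcl6 1.94-fold, the cation channel gene Trpm4 1.89-fold, the nucleoporin gene Nupl2 1.71-fold and the phospholipid-cleaving enzyme gene Gpcpd1 1.69-fold. Bhlhe41, a transcription factor gene of resident alveolar macrophages, was at 274 ± 37.8 against 143 ± 35.3 CPM and missed the threshold (adjusted p = 0.07). Leaving out 1 mouse ended several of these calls. By edgeR, Rsrp1 was not called without KO mouse 1 or 2 (adjusted p of 0.12 and 0.11) and Tsc22d3 without WT mouse 1 or 3 or KO mouse 1 or 2 (0.074 to 0.16). Hs3st3b1 (0.11 to 0.17) and Gpcpd1 (0.064 to 0.15) stayed called only without WT mouse 2, Napsa (0.073 to 0.19) only without WT mouse 1 and Nupl2 (0.066 to 0.17) only without KO mouse 3. Bcl6 (0.064 to 0.26) and Trpm4 (0.095 to 0.23) lost their calls whichever of the 6 mice was left out, and Luc7l and Plekho2 kept theirs.

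In all, edgeR called 69 genes in naive mice, 23 higher and 46 lower in KO, with 1053 at an unadjusted p under 0.05 where chance gives 632. The count was 18 without WT naive mouse 1, 20 without WT mouse 3, and 11, 15 and 20 without KO mice 1, 2 and 3. WT naive mouse 1 had 6.0% of its counts in Rn45s. Camera called 6 of 39 lists with small medians, and each had an adjusted p of 1 with an estimated correlation. Without WT naive mouse 1 camera called 0 lists, and without WT naive mouse 2 it called 3. Cholesterol synthesis was not called without KO mouse 3 (camera adjusted p = 0.25), sialic acid metabolism without WT mouse 3 (0.1) or KO mouse 2 (0.15), and immediate-early genes without KO mouse 2 (0.095). WT naive mouse 1 had the highest level of the ribosomal protein list among the WT naive mice (9.07 against 8.66 and 8.81 on the log2 scale) and of the oxidative phosphorylation list (6.95 against 6.51 and 6.62). The 6 lists called with all mice were ribosomal proteins (34 genes, median log2 fold change -0.18, camera adjusted p = 0.00079), oxidative phosphorylation (34 genes, -0.11, 0.027) and immediate-early and heat shock genes (16 genes, median -0.01, mean -0.29, 0.027), with the unfolded protein response (22 genes, 0.15, 0.012), cholesterol synthesis (24 genes, 0.13, 0.036) and sialic acid metabolism (20 genes, 0.17, 0.036). Of the 16 immediate-early and heat shock genes 2 fell over all genes tested, and 3 adjusted over the list alone.

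At day 7 after bleomycin edgeR called 1 gene between the genotypes, Siglecf, with 580 at an unadjusted p under 0.05. Genes can differ and miss the threshold here. Klk1b22, chosen after its values were seen, held counts in all 12 KO and 0 WT mice of the 4 times and was not called at day 7. DESeq2 called 15. Spp1, Gpnmb, C1qa and Ccr2 were not called. Cholesterol synthesis genes were slightly lower in KO mice: 23 of 24 had a negative log2 fold change, with a median of -0.26 and a camera adjusted p of 5.6e-08. The list was not called with an estimated correlation (adjusted p = 0.9), and 0 of its genes changed, either over all genes or adjusted over the list alone. Smaller shifts were called by camera for class I antigen presentation (-0.12), antioxidant genes (-0.12), the unfolded protein response (-0.15) and the cell cycle (0.12), each with an adjusted p of 0.9 with an estimated correlation. Without KO mouse 3 these 4 lists were not called (camera adjusted p = 0.064, 0.08, 0.14 and 0.51), and camera called 3 lists in place of 5. The class I and antioxidant lists were not called without WT mouse 1 either (0.18 and 0.6), nor the unfolded protein and cell cycle lists without WT mouse 3 (0.41 and 0.089), nor the cell cycle list without KO mouse 1 (0.17).

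At day 14, Gpnmb, Hpse and Cd300a were lower and Fcgrt was higher in KO than in WT samples. Gpnmb was at 1120 ± 250 CPM in KO and 2240 ± 179 in WT mice (1.99-fold lower, n = 3, edgeR adjusted p = 0.042). Hpse, which encodes heparanase, was 3.57-fold lower, at 22.1 ± 9.78 against 78.6 ± 19.2 CPM (adjusted p = 0.035). The phosphodiesterase gene Pde2a was 4.04-fold lower, the arginine deiminase gene Padi2 3.37-fold, the PILR-alpha ligand gene Pianp 2.47-fold and the inhibitory receptor gene Cd300a 1.7-fold. Fcgrt, which encodes the neonatal Fc receptor and lies near Siglecf on chromosome 7, was higher, at 390 ± 62.5 against 185 ± 43.6 CPM (2.11-fold, adjusted p = 0.046). Tbc1d14, a regulator of autophagy, was 1.43-fold higher. In all 17 genes were called, 4 higher and 13 lower, with 1269 at an unadjusted p under 0.05. This count rested on single mice: it was 242 without KO mouse 1 (67 higher, 175 lower), 2 without KO mouse 2 or KO mouse 3, 26 without WT mouse 1, and 1 without WT mouse 2 or WT mouse 3. That 1 gene was Siglecf, so Cd300a was not called without WT mouse 2 or WT mouse 3. Without WT mouse 2, WT mouse 3, KO mouse 2 or KO mouse 3 edgeR did not call Fcgrt (adjusted p of 0.2 to 0.37), Gpnmb (0.094 to 0.37), Hpse (0.089 to 0.28), Padi2 (0.094 to 0.28), Pde2a (0.094 to 0.33) or Pianp (0.11 to 0.37), nor Tbc1d14, which was not called without WT mouse 1 either (0.072 to 0.37).

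Whole groups of recruited, interstitial and fibrosis-associated macrophage genes leaned lower in KO mice at day 14, although few of their genes passed alone. Of 18 recruited genes 0 passed over all genes and 8 fell adjusted over the list alone (camera adjusted p = 1.2e-11; adjusted p = 0.19 with an estimated correlation). Of 13 interstitial genes 8 fell adjusted over the list alone (median log2 fold change -1.18, adjusted p = 1.8e-09; adjusted p = 0.19 with an estimated correlation). The 21 fibrosis genes had a median of -0.68, and Gpnmb was the 1 that fell either way (adjusted p = 1.7e-05; adjusted p = 0.19 with an estimated correlation). Per mouse, the recruited list averaged 4.59 ± 0.52 in KO and 5.52 ± 0.38 in WT mice on the log2 scale, without overlap (exact two-sided permutation p = 0.1, the smallest possible; chance gives no overlap in 10% of lists). KO mouse 1 lay next to the WT mice on the recruited list (5.12 against 5.2 to 5.94) and the fibrosis list (8.32 against 8.33 to 8.65), and KO mice 2 and 3 were lower, at 4.59 and 4.07 on the recruited list. These mice also lay nearer the naive mice on the first principal component, and the severity of injury in each mouse is not given in the sources used here. T and NK cell genes (median log2 fold change -0.96) and dendritic cell genes (-0.95) leaned lower with them, with a camera adjusted p of 0.5 and 0.19 with an estimated correlation, and without WT mouse 3 the T and NK list was not called at the preset correlation (0.18). C1qa was at 386 ± 245 against 988 ± 246 CPM (adjusted p = 0.32), Ccr2 at 50.5 ± 21.7 against 112 ± 35.6 (0.2) and the fractalkine receptor gene Cx3cr1 at 19.4 ± 12.1 against 65.4 ± 19.9 (0.11). The high-affinity Fc receptor gene Fcgr1 was at 90.3 ± 21.5 against 154 ± 21.6 CPM and missed the threshold (edgeR adjusted p = 0.059). Spp1, at 10800 ± 5310 against 13100 ± 1030 CPM, was not called (adjusted p = 0.9), nor was Trem2, at 212 ± 69.6 against 339 ± 31.6 (0.26).

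Other groups at day 14 went with these. Interferon-response genes were lower in KO mice (33 genes, median -0.85, camera adjusted p = 2.9e-17; adjusted p = 0.19 with an estimated correlation), and 11 fell adjusted over the list alone. Per mouse this list overlapped between genotypes (exact two-sided permutation p = 0.3), and KO mouse 1, at 4.79, lay above WT mice 1 and 2, at 4.58 and 4.76. Lysosome genes were lower (29 genes, -0.24, 7.4e-11; adjusted p = 0.19 with an estimated correlation), and 7 fell adjusted over the list alone. The 16 class I antigen presentation genes (median -0.26) and 19 chemokine genes (-0.68) had an adjusted p of 0.26 and 0.29 with an estimated correlation. Resident alveolar macrophage genes leaned higher (29 genes, 0.39, 3.1e-05; adjusted p = 0.26 with an estimated correlation), with 2 that rose and 1 that fell adjusted over the list alone. Car4, a carbonic anhydrase gene of resident cells, was at 968 ± 384 CPM in KO mice, 2.23 times the WT level, and missed the threshold (edgeR adjusted p = 0.15). Cholesterol synthesis genes leaned higher (24 genes, 0.26, 1.3e-07; adjusted p = 0.43 with an estimated correlation), and 0 passed either way. Ribosomal protein genes were also called higher (34 genes, 0.15, 0.0012; adjusted p = 0.78 with an estimated correlation), with 8.22, 8.62 and 8.74 in KO mice 1, 2 and 3 against 8.44, 8.32 and 8.44 in WT mice, and not without KO mouse 3 (camera adjusted p = 0.55). In all camera called 16 of 39 lists, 0 with an estimated correlation, and fry called 0.

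**Figure D3:**
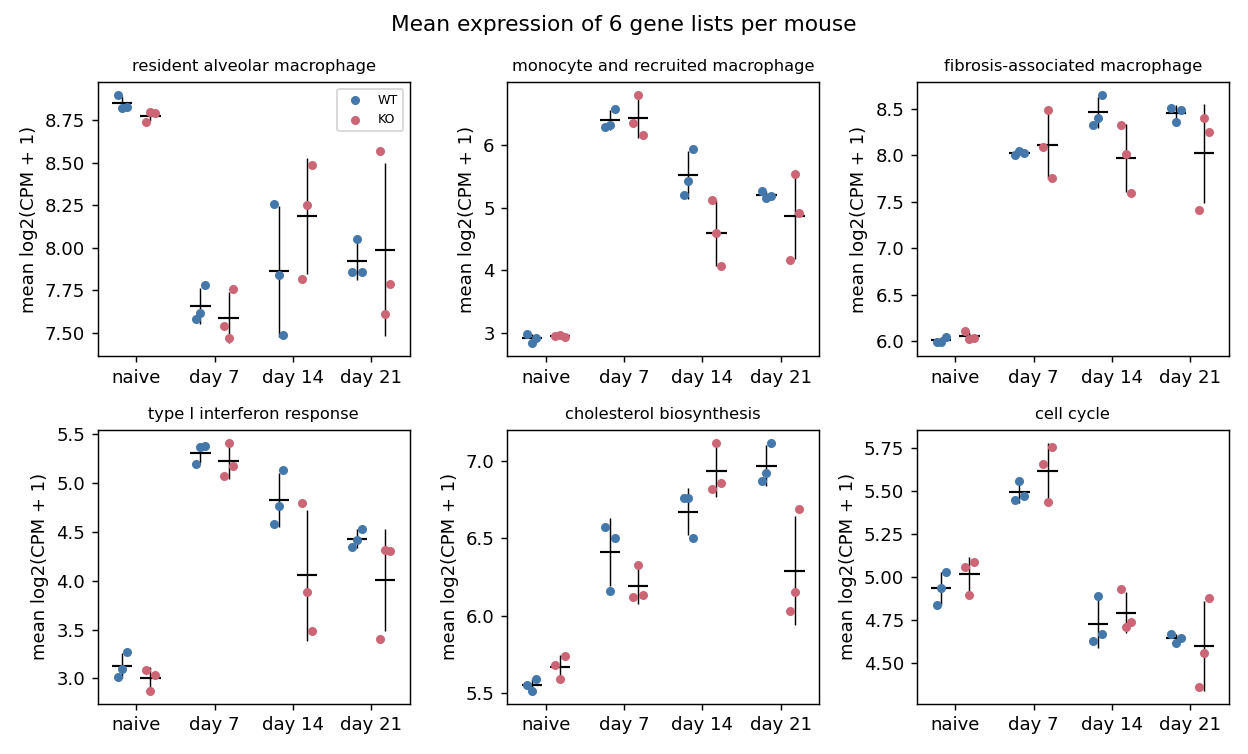
Mean log2(CPM + 1) over the genes of 6 fixed lists in each of the 24 mice by genotype and time; points are mice, horizontal bars group means and vertical bars SD. The recruited list at day 14 averages 4.59 in KO and 5.52 in WT mice, and the cholesterol synthesis list at day 21 averages 6.29 and 6.97.

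At day 21, Hmox1 was lower and Flna higher in KO than in WT samples. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was at 417 ± 60 CPM in KO and 1060 ± 429 in WT mice (2.55-fold lower, n = 3, edgeR adjusted p = 0.021). WT mouse 3 had the highest Hmox1, at 1560 CPM, and also the highest level of the hemoglobin gene Hba-a1, at 308 CPM. Without it the log2 fold change of Hmox1 was -0.97, from -1.35 with it, and Hmox1 was not called (edgeR adjusted p = 0.17), nor was it without KO mouse 1 (0.082) or KO mouse 2 (0.083). The list of erythrocyte and platelet genes averaged 1.5 ± 0.79 in KO and 3.07 ± 0.65 in WT mice on the log2 scale (exact two-sided permutation p = 0.2). The paired receptor gene Cd300ld was at 50.6 ± 7.32 against 80.7 ± 3.08 CPM (1.59-fold lower, adjusted p = 0.017), the heparan sulfate polymerase gene Ext1 was 1.57-fold lower and the magnesium transporter gene Nipa2, which lies between 10 and 20 Mb from Siglecf on chromosome 7, 1.41-fold lower. The actin crosslinker gene Flna was at 2340 ± 429 against 1260 ± 195 CPM (1.86-fold higher, adjusted p = 0.017). The secreted protein gene Kazald1 was 2.58-fold higher, Napsa 2.3-fold and the ubiquitin ligase gene Cbl 1.52-fold. In all 12 genes were called, 5 higher and 7 lower, with 1236 at an unadjusted p under 0.05. The count was 74 without KO mouse 3, 3 without WT mouse 1 or WT mouse 2, and 1 without WT mouse 3 or KO mouse 2. By edgeR, Cbl (adjusted p of 0.07 to 0.22), Ext1 (0.081 to 0.22) and Kazald1 (0.071 to 0.35) were not called without WT mouse 1, 2 or 3 or KO mouse 1 or 2, and Nipa2 (0.066 to 0.22) without WT mouse 1, 2 or 3 or KO mouse 2 or 3. Cd300ld (0.056 to 0.12) and Napsa (0.054 to 0.14) were not called without WT mouse 1, 2 or 3 or KO mouse 2, nor Flna (0.06 to 0.12) without WT mouse 2 or 3 or KO mouse 2. Retnla, a secreted product of alternatively activated macrophages, was at 0.0462 ± 0.0409 against 9.09 ± 8.57 CPM and missed the threshold (adjusted p = 0.064). Gpnmb was at 1140 ± 378 against 1830 ± 163 CPM (adjusted p = 0.16).

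Cholesterol synthesis genes leaned lower together at day 21. All 24 tested genes had a negative log2 fold change in KO against WT mice, with a median of -0.63 (camera adjusted p = 3.6e-41; adjusted p = 0.055 with an estimated correlation). Over all genes 0 fell, and adjusted over the list alone 24 fell. Fdps, which makes farnesyl diphosphate, was at 97.5 ± 31.4 against 196 ± 31.5 CPM (edgeR adjusted p = 0.059), and the lanosterol synthase gene Lss at 39.1 ± 9.18 against 69.9 ± 9.49 (0.058). Sc5d was at 44.8 ± 15.3 against 80.9 ± 8.98 CPM (adjusted p = 0.059) and Idi1 at 132 ± 46 against 254 ± 32.7 (0.064). Per mouse the list averaged 6.29 ± 0.35 in KO and 6.97 ± 0.13 in WT mice on the log2 scale (exact two-sided permutation p = 0.1). By fry the list moved down with an adjusted p of 0.0055, and so did 11 neutrophil genes (median -0.45, 0.0053), whose camera adjusted p was 0.0027 and 0.055 with an estimated correlation.

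Recruited, interstitial and fibrosis genes also leaned lower in KO mice at day 21. Medians were -0.29 for the recruited list (camera adjusted p = 0.019; adjusted p = 0.62 with an estimated correlation), -0.53 for the interstitial list (0.00049; adjusted p = 0.4 with an estimated correlation) and -0.33 for the fibrosis list (0.00083; adjusted p = 0.34 with an estimated correlation). Whether days 14 and 21 differ was not tested. These shifts rested on KO mouse 1. Without it the recruited list turned to the other direction (camera adjusted p = 0.89), and the interstitial (0.16) and fibrosis (0.25) lists were not called. Without WT mouse 1 the recruited list was not called (0.07). The differences in mean level went from -0.7 to -0.3 for the interstitial list and from -0.43 to -0.13 for the fibrosis list without KO mouse 1, and camera called 9 lists in place of 15. Antioxidant genes were lower (23 genes, -0.27, 1.5e-06; adjusted p = 0.34 with an estimated correlation): Hmox1 fell over all genes, and 3 fell adjusted over the list alone. Chemokine genes (19 genes, -0.65) had an adjusted p of 5.4e-07, and 0.16 with an estimated correlation, and 2 fell adjusted over the list alone. Lysosome genes (29 genes, -0.16) had an adjusted p of 7.6e-07, and 0.34 with an estimated correlation, with 4 that fell adjusted over the list alone. Without KO mouse 1 their difference in mean level went from -0.2 to -0.1 (camera adjusted p = 0.019). Class II antigen presentation was called in the other direction (14 genes, 0.52, 0.018, and 0.58 with an estimated correlation), and not without WT mouse 3 (0.15) or KO mouse 2 (0.78). KO mouse 2 had the highest class II level of the day 21 mice (7.15). It also had the highest levels of the B and plasma cell (1.22), dendritic cell (2.48) and T and NK cell (2.6) lists.

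Averaged over the 4 times, with 12 mice of each genotype, edgeR called 41 genes, 21 higher and 20 lower in KO. Fcgrt was 1.65-fold higher (edgeR adjusted p = 0.0012), Napsa 1.76-fold (8.3e-05), Trpm4 1.91-fold (2.2e-05), the calcium-binding protein gene Rcn3 2.48-fold, Myrf 2.21-fold and the netrin receptor gene Unc5a 1.7-fold. Erdr1 was 6.87-fold lower, Hpse 1.85-fold, Tmem254b 1.77-fold, the protein kinase A subunit gene Prkar2b 1.52-fold, the lectin gene Clec4d 1.51-fold, Gpnmb 1.36-fold and Cd300a 1.28-fold. Of the 24 fits without 1 mouse, 16 did not call Clec4d (edgeR adjusted p of 0.051 to 0.093), 18 Gpnmb (0.053 to 0.1) and 19 Myrf (0.053 to 0.097). Hpse was not called without WT naive mouse 2, WT day 14 mouse 3 or KO naive mouse 3 (0.05 to 0.071), nor Rcn3 without WT day 14 mouse 1, WT day 21 mouse 1 or 3, KO naive mouse 3 or KO day 14 mouse 3 (0.05 to 0.058). The count was 27 without WT naive mouse 3 or WT day 14 mouse 2, 26 without WT day 21 mouse 3, 23 without KO naive mouse 3, 24 without KO day 14 mouse 3 and 64 without KO day 14 mouse 1. Camera called 12 of 39 lists and 0 with an estimated correlation. Among these were interferon-response genes (33 genes, median -0.35, 2.3e-14; adjusted p = 0.35 with an estimated correlation; 7 fell adjusted over the list alone) and lysosome genes (29 genes, -0.12, 8.9e-09; adjusted p = 0.35 with an estimated correlation; 12 fell adjusted over the list alone).

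The averaged calls gathered beside Siglecf on chromosome 7, on 1 side of it. Within 10 Mb of the gene 13 of 136 tested genes were called (9.6%), against 25 elsewhere (0.21%), with Siglecf itself left out (Fisher's exact test, two-sided p = 1.1e-16). The 13 genes each kept 1 sign at all 4 times, 10 higher and 3 lower in KO. Choosing them by the average over these times favours this, so it is no separate support. All lay at higher coordinates than Siglecf, from Vsig10l (from 43463151) to Prmt3 (from 49778346). In this averaged comparison no tested gene at lower coordinates within 20 Mb was called. In naive mice Plaur and Dedd2, the latter chosen after its value was seen, were called lower in KO (log2 fold changes -0.78 and -0.78). Both lie at lower coordinates, between 10 and 20 Mb from Siglecf. The 13 include Napsa, Rcn3, Fcgrt (45092990 to 45103851) and Trpm4 (45302632 to 45333780). Chosen after their values were seen, Sult2b1 held 1051 counts over the WT and 12 over the KO libraries, and Kcnj14 held 12 over the WT and 447 over the KO libraries. Klk1b22, also chosen afterwards, held 0 counts in WT and 396 over the 12 KO libraries, at least 130-fold higher, although near-identical kallikrein genes leave its reads uncertain. The same enrichment was present among the calls of naive mice (8 of 136 in the window, 57 outside, p = 6e-07), day 14 (3 and 12, p = 0.00057) and day 21 (3 and 7, p = 0.00016), each by Fisher's exact test. At day 7 the test was empty, with 0 calls inside the window and 0 outside, Siglecf left out.

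**Figure D4:**
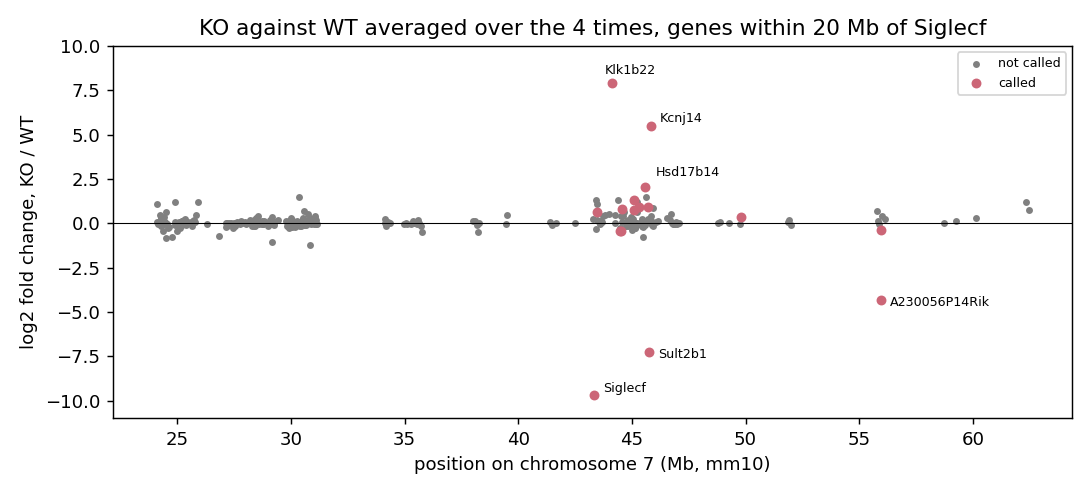
Log2 fold change of KO against WT averaged over the 4 times for tested genes within 20 Mb of Siglecf, by position on chromosome 7 in Mb, 1 point per gene, with called genes in red. Within 10 Mb of Siglecf 13 of 136 genes were called, all at higher coordinates than Siglecf.

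The response to bleomycin differed between genotypes in 1 gene at day 7, 42 at day 14 (27 higher, 15 lower) and 42 at day 21 (28 higher, 14 lower), with 776, 1299 and 1361 at an unadjusted p under 0.05. At day 14 the response of Tsc22d3 was higher in KO by 2.72 on the log2 scale, and that of Plekho2 fell by 1.26 relative to WT. In 32 of the 42 genes of day 14 and 31 of the 42 of day 21 the KO and WT groups differed more in naive mice than after bleomycin, and the test by which these genes were chosen contains the naive mice. Tsc22d3, for example, had a KO against WT log2 fold change of -1.8 in naive mice and 0.92 at day 14. Bhlhe41 had 0.94 in naive mice and -0.58 at day 14, and Kazald1 had -0.35 in naive mice and 1.37 at day 21. Camera called 2, 8 and 9 lists for this difference at days 7, 14 and 21, and 0 with an estimated correlation. The list count of day 7 was 4 without WT naive mouse 2, WT day 7 mouse 1 or KO day 7 mouse 3. That of day 14 was 14 without WT day 14 mouse 1 or KO day 14 mouse 1, and 7 without WT day 14 mouse 3. That of day 21 was 16 without WT naive mouse 3, 15 without KO naive mouse 2, 18 without KO day 21 mouse 2 and 17 without KO day 21 mouse 3. It was 6 without KO day 21 mouse 1. The counts of genes moved as well. The day 14 count was 24 without WT naive mouse 1, 10 without WT naive mouse 3, 19, 10 and 17 without WT day 14 mice 1, 2 and 3, 6, 19 and 23 without KO naive mice 1, 2 and 3, and 216, 7 and 8 without KO day 14 mice 1, 2 and 3. The day 21 count was 18 without WT naive mouse 1, 11 without WT naive mouse 3, 26, 11 and 0 without WT day 21 mice 1, 2 and 3, 9, 8 and 27 without KO naive mice 1, 2 and 3, and 27, 22 and 83 without KO day 21 mice 1, 2 and 3. The day 7 count was 3 without WT naive mouse 2 or KO day 7 mouse 1, 2 without WT day 7 mouse 2 or KO day 7 mouse 2, and 0 without KO naive mouse 1 or 2.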

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

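Chosen only after their results were seen were the tests of the called genes inside and outside the chromosome 7 window, of WT naive mouse 1 alone and of the Rn45s trend in naive mice, with both alternatives based on Rn45s.

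The results here stand out because the response to bleomycin differed between KO and WT mice by a test of that difference, in 1 gene at day 7, 42 at day 14 and 42 at day 21. At day 7 the gene was Luc7l, with a log2 difference in response of 1.72, chosen after its value was seen. At day 14 the responses were higher in KO for Hs3st3b1 (3.41), Rsrp1 (3.36), Tsc22d3 (2.72), Mxd1 (1.75), Rbm39 (1.64), Luc7l (1.59), Plaur (1.43) and the survival gene Mcl1 (0.86). They were lower for Bcl6 (-1.63), Bhlhe41 (-1.52), Plekho2 (-1.26), Cd300lb (-1.25), the adhesion gene Alcam (-1.18), the RNA sensor gene Tlr13 (-0.97) and Cd300a (-0.96). At day 21 they were higher for Rsrp1 (2.89), Cish (2.11), Ccdc117 (1.84), Egfem1 (1.82), Klf9 (1.81), Kazald1 (1.71) and Plaur (1.31), and lower for Bcl6 (-1.84), Bhlhe41 (-1.48), Cd300lb (-1.33), Fhl3 (-1.24), Plekho2 (-1.19) and Lss (-1.13). The median size of the KO against WT difference in the 42 genes of day 14 was 0.77 in naive mice and 0.45 at day 14, and in those of day 21 it was 0.65 and 0.37. The naive mice enter every one of these tests, and 25 and 24 of the genes were also called in naive mice.

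Of 100 splits of the mice, the real one included, 1 gave as many genes as the 42 of day 14, with 22 in the highest other. For the 42 of day 21 it was 1 of 100 as well, with 15 in the highest other. Relabelling these mice thus seldom gave such counts. It cannot exclude chance in which 3 mice entered each group. For the 1 gene of day 7, 10 of 100 splits gave as many, so chance cannot be excluded. The highest other split gave 126 where the median of the others was 0, and why was not tested. Leaving out 1 mouse moved the counts of days 14 and 21 as far as 6 (without KO naive mouse 1) and 216 (without KO day 14 mouse 1) and 0 (without WT day 21 mouse 3) and 83 (without KO day 21 mouse 3).

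Gene lists also differed in response by camera with the preset correlation, and each missed the threshold with an estimated correlation. At day 7 cholesterol synthesis was lower in KO (median difference -0.42, adjusted p = 0.99 with an estimated correlation), as was the unfolded protein response (-0.27, 0.99). At day 14 the recruited (-1.25, 0.6), interstitial (-1.14, 0.6), fibrosis (-0.68, 0.6), lysosome (-0.21, 0.61), interferon (-0.54, 0.83) and sialic acid (-0.31, 0.6) lists were lower, and the resident (0.38, 0.62) and ribosomal protein (0.3, 0.85) lists higher. At day 21 the interstitial (-0.77, 0.71), fibrosis (-0.35, 0.71), cholesterol (-0.76, 0.26), lysosome (-0.15, 0.71), chemokine (-0.7, 0.71), unfolded protein (-0.32, 0.42), antioxidant (-0.17, 0.71) and sialic acid (-0.24, 0.42) lists were lower and ribosomal proteins higher (0.25, 0.71). In the cholesterol list of day 21, Lss fell over all genes, and 20 of 24 genes fell adjusted over the list alone. Without KO day 21 mouse 1 the interstitial (camera adjusted p = 0.23), fibrosis (0.23), lysosome (0.17), chemokine (0.065) and sialic acid (0.17) lists of day 21 were not called. The interstitial list was not called without WT naive mouse 2 (0.067) or WT day 21 mouse 1 (0.058) either, nor the sialic acid list without WT day 21 mouse 1 (0.058). The antioxidant list of day 21 was not called without WT naive mouse 2 (0.1), WT naive mouse 3 (0.085) or WT day 21 mouse 3 (0.051), nor the ribosomal protein list without WT naive mouse 1 (0.09). At day 14 the resident list was not called without WT day 14 mouse 3 (0.066), nor the sialic acid list without KO day 14 mouse 3 (0.052).

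The lower recruited and fibrosis-associated lists of KO mice at day 14 were weighed against RNA quality and cell composition. With the Rn45s share as a covariate the median of the recruited list was -1.16, which argues against RNA quality as traced by that share alone, and other differences in RNA quality stay open, since ribosomal protein genes were higher in KO mice 2 and 3 (8.62 and 8.74 against 8.32 to 8.44 in WT mice). A lower share of recruited cells with no change within them may account for the pattern. It was weighed over 65 genes with at least 20 CPM in WT mice at day 14 and under 5% of that in naive mice. The spread of their log2 fold changes was 1.05 times their median SE, around a median of -1.06. This test is lenient, since the SE contains the spread between mice that such genes share. Choosing genes by their WT level at day 14 also lowers the median by itself, so the median is no support. How severe the injury was in each mouse is not given in the sources used here and stays open, since KO mice 2 and 3, at 3.5 and -19 on the first component, carry most of the shift. Loss of Siglec-F, the order of the libraries and the genes near Siglecf go with genotype and stay open too, and the 17 calls of day 14 became 242 without KO mouse 1, 26 without WT mouse 1, 2 without KO mouse 2 or 3 and 1 without WT mouse 2 or 3.

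The calls beside Siglecf on chromosome 7 were weighed against alleles of the strain in which the gene was targeted, carried along with it. Those within 10 Mb all lay at higher coordinates than Siglecf, and what this means for such alleles was not tested. Of the averaged calls with a position 34.2% lay within 10 Mb, over the 10% that argues against such alleles but short of most calls, so for all 41 calls this stays undecided. For the calls inside the window the enrichment (Fisher's exact p = 1.1e-16) is consistent with such alleles, or with an effect of the targeting on neighbouring genes, which was not tested. For the calls outside the window it stays open: that 21 lie on other chromosomes decides nothing, since leaving out the window nearly fixes this and alleles near Siglecf could act on genes elsewhere, and of 4 on chromosome 7 Nipa2 (from 55931287) and A230056P14Rik (from 55962531) lie between 10 and 20 Mb from Siglecf. The count of 41 was 64 without KO day 14 mouse 1, 27 without WT naive mouse 3 or WT day 14 mouse 2, 26 without WT day 21 mouse 3, 24 without KO day 14 mouse 3 and 23 without KO naive mouse 3, and 1 of 100 splits, the real one, gave as many, with 16 in the highest other.

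The 69 genes called between naive KO and WT mice were weighed against RNA quality and the state of the mice at collection. Without WT naive mouse 1, whose Rn45s share was 6.0%, 18 of 69 genes were called, but the counts without WT mouse 3 (20) and KO mice 1, 2 and 3 (11, 15 and 20) were as low, so this decides nothing. Fold changes of 68 of the 69 genes, Siglecf left out, were 0.91 without that mouse of those with it (median ratio), and 1.02 with the Rn45s covariate. These 68 genes were chosen by their calls with that mouse included, which favours genes that do not rest on 1 mouse. The 0.91 therefore cannot exclude a difference carried by that mouse alone. The 1.02 argues against the Rn45s trend for these genes only. Mean Rn45s shares, 3.11% in WT and 3.21% in KO naive mice, left the covariate little to move. Lower glucocorticoid exposure or another hour of collection in KO mice may contribute but cannot be told apart from genotype here: the median of 9 glucocorticoid-induced genes was -0.4, between the bounds set, with 9 lower and 0 called. Genes whose values had been seen were kept out of this list. The 0 therefore does not cover Tsc22d3, the glucocorticoid-induced leucine zipper gene, which was called lower in naive KO mice (log2 fold change -1.8). Clock genes do not settle the hour: the listed Per and output genes had a median of 0.26 and those of the Arntl arm 0.02, with 0 called in each. Dbp, a clock output gene outside these lists and chosen after its value was seen, was called higher in naive KO mice. Its log2 fold change was 1.74 (edgeR adjusted p = 0.045). It lies within 10 Mb of Siglecf (from 45705088), so it does not settle the hour either. Loss of Siglec-F stays open as well.

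For the remaining counts the splits of 3 mice against 3 number 10, too few for a share under 0.05, and in each the real split was the 1 with as many genes. The highest other split gave 0 for KO against WT at naive (real 69), day 7 (real 1), day 14 (real 17) and day 21 (real 12). After bleomycin it gave 1053 for WT day 7 (real 4481), 0 for WT day 14 (4059), WT day 21 (4102), KO day 7 (4308) and KO day 14 (2132), and 9 for KO day 21 (2765).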

How the results depend on the processing

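Chosen only after results were seen were the Rn45s covariate and the fit without both libraries of high Rn45s share (WT naive mouse 1 and WT day 7 mouse 1).

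Leaving out 1 library at a time, the counts of KO against WT ranged from 11 to 73 in naive mice, 1 to 1 at day 7, 1 to 242 at day 14, 1 to 74 at day 21 and 23 to 64 averaged. Counts after bleomycin ranged from 3646 to 4296, 2944 to 3575 and 3036 to 3619 in WT mice at days 7, 14 and 21, and from 3375 to 3968, 1276 to 2310 and 1735 to 3804 in KO mice. Response differences ranged from 0 to 3, 6 to 216 and 0 to 83, and the correlation of the WT and KO responses from 0.84 to 0.88, 0.73 to 0.82 and 0.81 to 0.85. Of 1968 single-gene results 1561 stayed called and 407 lost the call with fewer samples. Of 1614 list results 1515 stayed called, 97 lost the call and 2 reversed: oxidative phosphorylation in naive mice without WT naive mouse 1 (adjusted p = 0.52; 8.9e-06 to 0.52 over all libraries left out) and recruited genes at day 21 without KO day 21 mouse 1 (adjusted p = 0.89; 6.7e-07 to 0.89 over all).

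DESeq2 called more genes than edgeR: 163, 15, 143, 132 and 150 for KO against WT at naive, day 7, day 14, day 21 and averaged, and 39, 214 and 262 for the response differences. Limma-voom called 34 at day 14, 22 at day 21 and 3 for the response difference of day 7. Without an expression filter 2 were called at day 7, 22 at day 21 and 3 for the response difference of day 7, and RLE scaling gave 2 for the last. The cause of these differences was not tested. A model of the compared groups alone, with fewer samples, gave 31 in naive mice, 3 at day 14, 3 at day 21, 1391 for KO day 21 after bleomycin and 3, 8 and 22 for the response differences.

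With the mouse number as a block the naive count was 38 and that of day 14 was 8, and 244 of 264 single-gene results stayed called. The labels do not pair the mice. In WT mice at day 14 after bleomycin each library correlated best with its own number, and in no comparison did all same-number correlations exceed 0.1.

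Without both libraries of high Rn45s share, 28 genes were called in naive mice and 0 for the response difference of day 7, and oxidative phosphorylation reversed in naive mice (adjusted p = 0.48). The Rn45s covariate gave 133 in naive mice, 24 at day 21 and 2, 131 and 93 for the response differences. With it the list calls went from 6 to 3 in naive mice, from 5 to 2 at day 7 and from 2 to 4 for the response difference of day 7, and without both libraries from 6 to 0 in naive mice. The cause was not tested.

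With an estimated correlation 28 of the 214 list calls stayed, and fry kept 137. Correlation over genes called in WT was 0.94, 0.91 and 0.92 at days 7, 14 and 21. Of 264 single-gene results 264 stayed called by DESeq2, 222 by voom, 262 without a filter, 262 with RLE, 261 with the covariate and 260 on thinned counts. For bleomycin at days 14 and 21 the median of all genes was -0.1 to -0.12 scaled by library totals, 0 to 0.01 with TMM and 0.01 to 0.02 with RLE. Runs 1 and 2 were not analysed separately, since the table has 1 column per mouse.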

Other observations

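The test of glucocorticoid-induced genes used lists written before their values were seen; the named genes Per1, Fkbp5 and Hba-a1 were chosen after.

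Cell cycle genes moved both ways after bleomycin. In WT mice 23 of 37 rose at day 7, among them the mitotic kinase gene Plk1 at 2.47-fold and the survivin gene Birc5 at 2.2-fold (camera adjusted p = 8.5e-06; adjusted p = 0.25 with an estimated correlation), and 14 fell at each of days 14 and 21. The replication licensing genes Mcm5 and Mcm6 were 1.68-fold and 1.6-fold lower at day 14 and 2.17-fold and 1.99-fold lower at day 21. In KO mice 26 rose at day 7, and 11 and 18 fell at days 14 and 21. Ribosomal protein genes fell past the threshold in WT mice in 3, 24 and 30 of 34 at days 7, 14 and 21, and in KO mice in 2, 0 and 4. Mean levels of the list on the log2 scale fell in both genotypes. They went from 8.85 to 8.61, 8.4 and 8.3 in WT mice and from 8.68 to 8.58, 8.53 and 8.36 in KO mice. The counts also depend on the spread between mice, so they do not compare the genotypes.

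Markers of other airway cells rose with bleomycin. Of 19 T and NK cell genes 19, 16 and 17 rose in WT mice at days 7, 14 and 21, with Il7r at 144-fold, 148-fold and 131-fold, and 18, 15 and 19 rose in KO mice. Of 16 dendritic cell genes 12, 11 and 12 rose in WT mice, and of 19 alveolar epithelial genes 10, 8 and 14. At day 14 the medians of KO against WT were -0.96 for the T and NK list and -0.95 for the dendritic cell list, with an adjusted p of 0.5 and 0.19 with an estimated correlation. At day 21 Hba-a1, a hemoglobin gene, was at 27.4 ± 15.4 CPM in KO and 165 ± 124 in WT mice.

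In WT mice 12, 12 and 13 of 19 chemokine genes rose at days 7, 14 and 21, 11, 11 and 11 of 16 complement genes, 19, 21 and 23 of 28 matrix genes, 14, 12 and 11 of 22 glycolysis genes and 13, 10 and 8 of 25 p53 target genes. For 6 lists camera made no call in the 14 comparisons. Their lowest adjusted p was 0.062 for apoptosis (26 genes), 0.075 for LXR targets (19), 0.23 for NF-kB and inflammatory cytokines (20), 0.22 for airway epithelium (10), 0.15 for endothelium (5) and 0.11 for fibroblasts and mural cells (6).

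Among the 9 listed glucocorticoid-induced genes in naive mice, Per1 had a KO against WT log2 fold change of -1.57 and Fkbp5 of -0.45, and neither was called. The 7 tested genes of the Per and output list of the clock, which does not hold Dbp, had a median of 0.26.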
